A study of Mus musculus with 2 samples.

How the data were processed

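DNase-seq was carried out on cerebellum of 2 female B6CASTF1/J mice aged 25 days, and each library was analysed on its own. The labels number the libraries as biological replicates 1 and 2 and give the animals different numbers, but both carry the same donor identifier. That the replicates are separate animals therefore rests on the labels' descriptions, and any spread between them is that of 2 libraries. There is a single group, so no test between conditions was made. All errors are SDs over 2 replicates.

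Per the labels, the assembly was mm10, and the deposited file notes say that the files of each library were derived from its own filtered alignments, so replicates were not pooled. The aligner, the peak and footprint callers and their versions are not given in the sources used here. The mice are hybrids and mm10 is the C57BL/6J sequence, so reads from the CAST/EiJ chromosomes could align less often where the strains differ; no allele information was used here. Each library has a shorter and a longer peak list. Tested against the deposited FDR values, every peak of the shorter list touches a position at an FDR of 0.001 or lower, and every peak of the longer list touches a position at 0.05 or lower. The shorter list was used throughout unless the longer list is named. The value of a peak is the authors' own signal in the deposited lists, with no stated scale. Within a tolerance of 0.05 of a step, 100% of the values were whole multiples of a single step per library. If the values are cleavages scaled to a total of 1000000, the step gives the depths in the report. This scale is an inference, no count test was run on it, and the median peak would then hold 250 cleavages in replicate 1 and 225 in replicate 2. The deposited FDR files give a false discovery rate of local cleavage, a p-value-like quantity, and list only positions under 0.05. The deposited footprint files give intervals and the constant 0.01, which was read as the authors' threshold and not used as a measurement.

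Some peaks overlap another peak of the same list, 3634 (3.38%) in replicate 1 and 1652 (2.18%) in replicate 2, and they were kept as deposited. Covered lengths count each base once. The shorter list is not wholly inside the longer list: 98.1% and 98.6% of its peaks overlap a peak of the longer list. Gene models were those of GENCODE vM21, with 21938 protein-coding genes, and sequence was that of the reference GRCm38.p6 assembly, which has the chromosome coordinates of mm10. Coordinates are counted from 1.

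A promoter peak was a peak that overlapped a window of 500 bp either side of the TSS of any annotated transcript of a gene, and the promoter value was the highest value of such peaks, or 0. The peak can thus lie at an alternative start site, and it can differ between replicates or belong to a neighbour. The 5' end of a gene is here the outermost end of its annotated gene model, and an alternative start site is any other annotated one. The outermost end need not be the main promoter. Peaks were called shared at an overlap of 1 bp or more, and chance overlap was measured after moving peaks 1 Mb along the chromosome. The gene lists were granule neuron, granule progenitor and cell cycle, Purkinje cell, cerebellar interneuron and unipolar brush cell, astrocyte and Bergmann glia, oligodendrocyte lineage, microglia, endothelial and mural, choroid plexus, forebrain, hepatocyte, blood, skeletal muscle, Hox, anterior hindbrain, immediate early, imprinted, housekeeping and a sex check. The lists, the motifs, the tests, the rule for named genes and the first alternatives were fixed before the data were examined. The members of each of 18 lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, in each library, with Benjamini-Hochberg adjustment over 36 tests and a threshold of 0.05. Imprinted genes that are not protein-coding were left out of the test. Odds ratios had 0.5 added to each cell.

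Peaks within 50 kb of the 5' end of each gene were counted, and the list median was placed among 10000 random lists of the same size matched on gene density in 10 bins. Lists were called outside random lists below percentile 2.5 or above 97.5. The log2 ratio of promoter values between replicates was centred on all shared peaks (0.07) and placed among random lists matched on mean value. It was computed for the 12 lists with at least 3 shared promoter peaks. Footprints were extended by 5 bp on both sides and searched on both strands for 27 consensus motifs. Control windows were the footprints moved 75 bp to a random side, without overlap of any footprint. Shares with a match were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over motifs and replicates.

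The named genes are, for each list, the 2 members with the highest mean promoter value and up to 2 members without a promoter peak in either library, in alphabetical order. They are also the 10 protein-coding genes with most shared peaks within 50 kb, and the genes nearest to the 5 strongest peaks of each replicate that overlap no peak in either list of the other. For a list with fewer such members all are named. Some genes that the rule selects are not reported here. The Neurod2 and Cerkl genes, all 4 Y-linked genes of the sex check, and the escape genes of the closing section are named outside this rule, and Neurod1 was picked for the map from among the named genes.

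The alternatives were a reciprocal overlap of 50%, the 50000 strongest peaks, the longer list, windows of 1000 bp and 100 kb, TSS of all gene types, distal peaks over 1 kb from every TSS, random lists matched on promoter CpG or not matched, autosomes alone, FDR thresholds of 0.001 and 0.05, other footprint controls, and each replicate left out. Promoter calls from FDR positions or from the 5' end of the gene alone, and merging of overlapping peaks, were added after seeing the data. Poisson and exact binomial intervals are at 95% and cover counting error only. For the closing section, Y peaks were searched against the other chromosomes with a word length of 28 bp, and intervals of medians come from 1000 bootstrap draws over peaks or genes of a library.

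The statistics were tested on simulated data. For peak sharing, 59.67% was simulated and 59.67% recovered. For the promoter test on 21938 genes and lists of 16, 5.2% of 500 random lists passed at an unadjusted 0.05, and 98.0% of lists with a promoter rate of 15% did. Of 100 random lists, 6% lay outside the central 95% of matched lists, and 100% of 1026 planted motifs were found. The tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1 and BLAST+ 2.17.0.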

Results

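Accessible chromatin was mapped by DNase-seq, in which the nuclease DNase I cleaves open DNA and the cleaved ends are sequenced. The tissue was the cerebellum of 2 female B6CASTF1/J mice aged 25 days, hybrids of the inbred strains C57BL/6J and CAST/EiJ. The labels give these as biological replicates 1 and 2 of a single group. There is therefore no contrast between conditions, and the comparisons below are between parts of the genome or between the 2 libraries. Replicate 1 had 107483 peaks and replicate 2 had 75658, a mean of 91571 ± 22504 (SD, n = 2). The peaks covered 26.1 Mb and 16.5 Mb of the mm10 genome. At a false discovery rate (FDR) of 0.01 or lower, 57.3 Mb was called in replicate 1 and 35.7 Mb in replicate 2 (46.5 ± 15.3 Mb, SD, n = 2). The scale of the peak values is not given in the sources used here. If they are cleavages scaled to a total of 1000000, their step implies a depth of 290.3 times that total in replicate 1 and 185.4 times in replicate 2, a ratio of 1.57.

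All 20 genes in the list of cerebellar granule neurons, the small excitatory neurons of the cerebellar cortex, had a promoter peak in both animals. Among all other protein-coding genes the share was 64.1% in replicate 1 and 60.7% in replicate 2. The highest values of the list were at Cbln3, a cerebellin family member (14.0 ± 5.08, SD, n = 2), and at Neurod1, a transcription factor of neuronal differentiation (13.2 ± 4.90). The median promoter value of the list was 4.31 and 5.43. It was not outside random lists of the same size matched on promoter CpG content (percentiles 29.1 and 68.0). By this median, housekeeping genes lay above such lists in both libraries. The Purkinje cell, interneuron and unipolar brush cell, forebrain, Hox and anterior hindbrain lists lay below them in both. The Cbln3 peak spans 55884221 to 55884420 of chromosome 14 in replicate 1. All 15 immediate early genes, which respond to neuronal activity, had a promoter peak in both animals, with the highest values at Jun (17.1 ± 5.97) and Dusp1 (15.7 ± 3.30). So did all 18 housekeeping genes, with the highest values at Rplp0, a ribosomal protein gene (22.2 ± 1.27), and Ppia (16.8 ± 0.853). Of 14 genes of granule progenitors and the cell cycle, 14 had a promoter peak in replicate 1 and 13 in replicate 2. Their highest values were at Top2a, a DNA topoisomerase (8.24 ± 0.386), and Cdk1, a mitotic kinase (7.12 ± 1.31).

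These 4 lists lay above the other genes in each library by Fisher's exact test (two-sided, Benjamini-Hochberg over 36 tests; genes are not independent replicates). The adjusted p of the exact test was 0.00083 and 0.00049 for granule neurons, and 0.0038 and 0.0022 for immediate early genes. It was 0.0021 and 0.00065 for housekeeping genes, and 0.0058 and 0.019 for granule progenitors. Among random lists matched on promoter CpG content, granule neuron genes lay at percentiles 99.96 and 99.985, and the other 3 lists lay inside the central 95% in both libraries. Each of these 3 was at the maximum of 100% in replicate 1, which lay at percentile 83.53 or lower of such lists, so none could have stood above them in both libraries. Granule progenitors also missed the threshold in replicate 1 among the 50000 strongest peaks (adjusted p = 0.14, exact test). The Dusp1 value belongs to a peak at an annotated start site, 26508561 to 26508820 of chromosome 17, while the outermost 5' end of the gene model is at 26562128. Which of these is the main promoter was not tested. In windows at the outermost 5' end of each gene alone, the immediate early list missed the threshold in replicate 2 (12 of 15 genes, adjusted p = 0.11, exact test). Dusp1 was among the genes without a peak there, so this setting can miss a promoter inside the gene model.

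Promoters of 7 lists had a peak less often than other genes in both libraries. Of 16 microglial genes, 2 had a promoter peak in replicate 1 and 3 in replicate 2. Irf8, a transcription factor of myeloid cells, stood at 1.93 ± 0.503 (SD, n = 2), and Aif1 and C1qa had no peak. Of 20 endothelial and mural genes, 6 and 4 had a peak. Col1a1, a collagen gene, stood at 3.70 ± 1.09, at an alternative start site, and Kdr, a receptor for vascular endothelial growth factor, at 0.699 ± 0.249, and Abcc9 and Acta2 had no peak. Among 9 choroid plexus genes only Otx2 had a promoter peak, at 1.56 in replicate 1 and 1.203 in replicate 2, while Aqp1 and Clic6 had none. The Otx2 values come from different peaks, starting at 48665941 and 48667461 of chromosome 14.

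Of 19 hepatocyte genes, Tdo2 alone had a promoter peak (0.406), in replicate 1, at an alternative start site. Ahsg and Alb, which encode plasma proteins, had none. Of 12 blood genes, 1 had a peak in each library, and Alas2 had none. Of 12 skeletal muscle genes, Mylpf and Actn2 had a peak in both animals and Acta1 and Ckm had none. Actn2 stood at 1.94 ± 0.175 (SD, n = 2), and Mylpf at 5.28 in replicate 1 and 8.43 in replicate 2, from peaks that do not overlap. Of 39 Hox genes, which pattern the trunk and posterior hindbrain, 5 had a promoter peak in replicate 1 and 1 in replicate 2. The highest values were at Hoxa7 (3.28 ± 1.84) and, in replicate 1 alone, at an alternative start site of Hoxc5 (0.820), and Hoxa10 had none.

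By the same exact test the adjusted p was 0.00023 and 0.0025 for microglia, 0.0060 and 0.00095 for endothelial and mural genes, and 0.0036 and 0.0058 for choroid plexus. It was 1.1e-06 and 2.3e-07 for hepatocytes, 0.00053 and 0.00094 for blood, 0.0025 and 0.0045 for skeletal muscle, and 8.8e-10 and 3.1e-13 for Hox genes (exact test). With the longer peak list, choroid plexus, endothelial and mural, and skeletal muscle genes no longer passed in both libraries, nor did skeletal muscle genes with promoter windows of 1000 bp. Among lists matched on promoter CpG content, blood genes were inside the central 95% in both libraries (percentiles 12.01 and 19.07). Microglial (0.735) and skeletal muscle genes (1.03) were below it in replicate 1 alone, and hepatocyte genes (0.955) in replicate 2 alone.

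**Figure D1:**
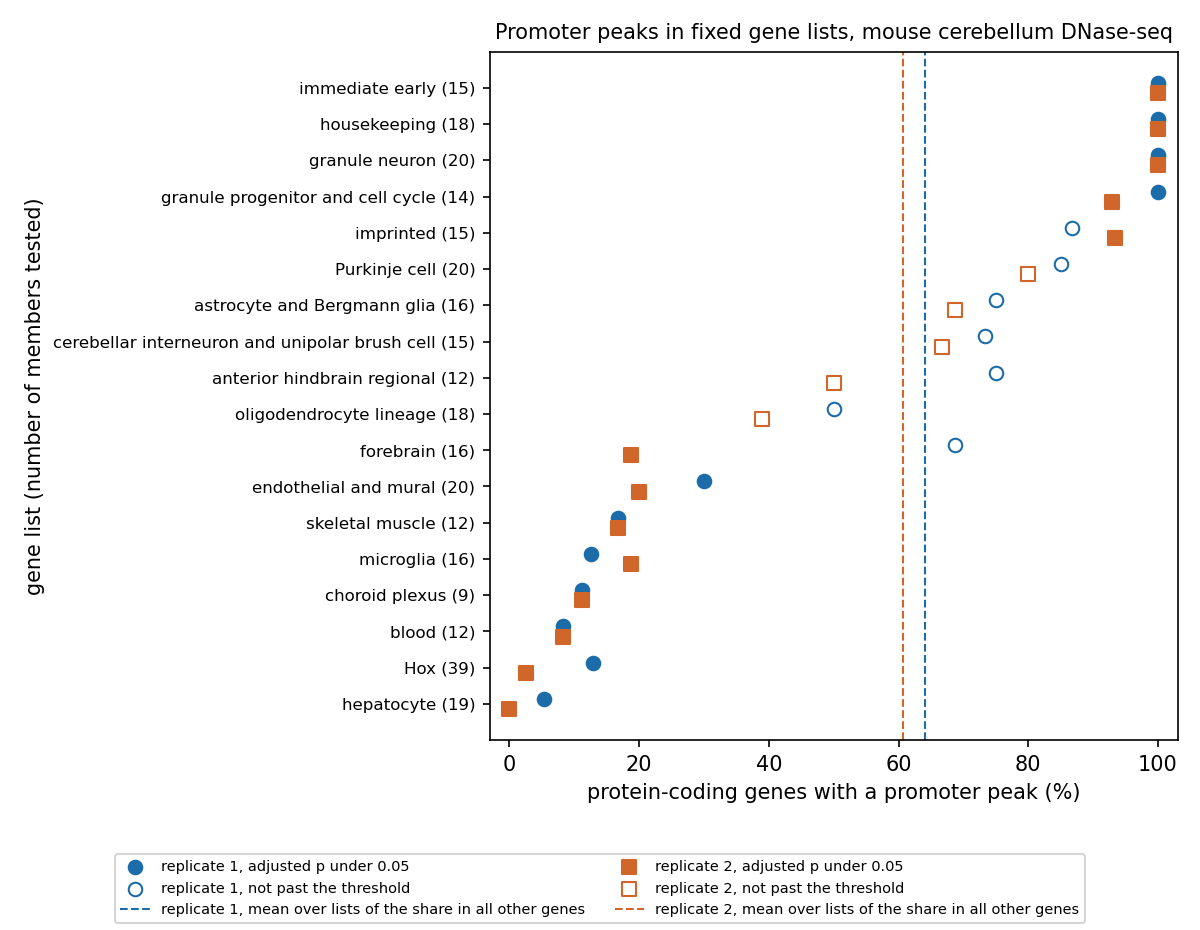
Percent of the genes of each fixed list with a promoter peak (x axis) in replicate 1 (circles) and replicate 2 (squares), filled where the adjusted p of Fisher's exact test is under 0.05; dashed lines show the share in all other protein-coding genes, averaged over lists. Granule neuron genes lie at 100% in both libraries, and Hox genes at 12.8% and 2.56%.

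Other cerebellar lists did not pass this test in either library. Of 20 genes of Purkinje cells, the output neurons of the cerebellar cortex, 17 and 16 had a promoter peak (adjusted p = 0.088 and 0.14, exact test). The highest values were at Itpr1, a calcium release channel (9.44 ± 1.63, SD, n = 2), and Lhx1, a homeobox gene (8.40 ± 0.0996), and Pcp2 and Ppp1r17 had no peak. Of 15 genes of cerebellar interneurons and unipolar brush cells, 11 and 10 had a peak (adjusted p = 0.65 and 0.80, exact test). Cdh22 stood at 3.94 ± 0.927 and Prkcd at 1.91 ± 0.305, and Gad1 and Pax2 had none. Among lists matched on promoter CpG content this list was below the central 95% in both libraries, at percentiles 1.85 and 1.68.

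Of 16 genes of astrocytes and Bergmann glia, 12 and 11 had a promoter peak (adjusted p = 0.53 and 0.65, exact test). With the longer peak list these genes lay above other genes in replicate 2 alone (adjusted p = 0.33 and 0.030, exact test). Aldoc, a glycolytic enzyme, stood at 4.29 ± 1.56 (SD, n = 2) and Gfap, an intermediate filament protein, at 3.55 ± 1.02, and Aldh1l1 and Aqp4 had none. Of 18 genes of the oligodendrocyte lineage, 9 and 7 had a peak (adjusted p = 0.28 and 0.12, exact test). Mbp, a structural protein of myelin, stood at 2.30 ± 0.465 and Olig1 at 1.87 ± 0.206, and Aspa and Cspg4 had none. Among the 50000 strongest peaks the oligodendrocyte list was below other genes in both libraries (adjusted p = 0.027 and 0.041, exact test). Of 12 regional genes of the anterior hindbrain, 9 and 6 had a peak (adjusted p = 0.63 in each library, exact test). Among lists matched on promoter CpG content the anterior hindbrain list lay at percentiles 2.54 and 0.02, below the central 95% in replicate 2 alone, and the oligodendrocyte list at 7.32 and 1.16, likewise. En2, a homeobox gene, stood at 9.89 ± 3.31 and Meis1 at 8.12 ± 1.17, and Gbx2 and Lmx1b had none.

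A pair of lists passed in replicate 2 alone. Of 16 forebrain genes, 11 had a promoter peak in replicate 1 and 3 in replicate 2 (adjusted p = 0.80 and 0.0025, exact test). Drd1, a dopamine receptor, stood at 2.85 ± 1.19 (SD, n = 2), and Dlx1 and Dlx2 had none. The forebrain list was below other genes in both libraries among the 50000 strongest peaks, and below the central 95% of lists matched on promoter CpG content (percentiles 0.66 and 0). With the longer peak list it no longer passed in replicate 2 (adjusted p = 0.14, exact test). Of 15 imprinted protein-coding genes, 13 and 14 had a promoter peak (adjusted p = 0.14 and 0.012, exact test). At the 5' end of the gene alone 9 had a peak in each library and the list did not pass (adjusted p = 0.83 in replicate 2, exact test), nor did it stand above lists matched on promoter CpG content (percentile 88.755 in replicate 2). With positions at an FDR of 0.001 in place of peaks it passed in both libraries (adjusted p = 0.038 and 0.021, exact test). Peg3 stood at 7.01 ± 2.82 and Snrpn, at an alternative start site, at 7.01 ± 0.117, and Ndn had no peak. Of 5 genes checked for sex, Xist, the RNA of X inactivation, had a peak in both animals (0.837 ± 0.0542), and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had none.

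Granule neuron genes had the most peaks around them of the 18 lists. Within 50 kb of the TSS their median was 34 peaks in replicate 1 and 18 in replicate 2, against 5 and 3.5 in random lists matched on gene density (percentile 100 in both). Immediate early genes had medians of 19 and 13, housekeeping genes 15 and 11.5, and skeletal muscle genes 15 and 11, each at percentile 99.87 or above in both libraries. Hox genes had fewer peaks than matched lists, 5 and 2 against 11 and 9 (percentiles 0.06 and 0). The windows also hold neighbouring genes. Hox genes lie in clusters, so their windows overlap and count many of the same peaks. Random lists were drawn gene by gene, so the Hox percentiles may be too extreme. Counting only peaks over 1 kb from every TSS, housekeeping genes stood above random lists in replicate 2 alone, with medians of 5 and 4.5 against 2.5 and 2 (percentiles 97.01 and 99.72), a ratio to random lists like that for all peaks. Hox genes were then not below random lists in either library, and against unmatched lists Hox genes lay below in replicate 2 alone (percentile 0.56).

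The other lists were not outside the central 95% of random lists in both libraries. The medians were 9 and 7 peaks for granule progenitors, 6 and 4.5 for Purkinje cells, 7 and 4 for interneurons and unipolar brush cells, and 6.5 and 4.5 for astrocytes and Bergmann glia. They were 8 and 5 for oligodendrocytes, 5.5 and 5.5 for microglia, 4 and 3 for endothelial and mural genes, and 8 and 5 for choroid plexus. Forebrain genes had 5.5 and 2, hepatocyte genes 5 and 3, and blood genes 4.5 and 4.5. Anterior hindbrain genes (7.5 and 4.5) lay above the range in replicate 1 alone, and imprinted genes (8 and 7) in replicate 2 alone.

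**Figure D2:**
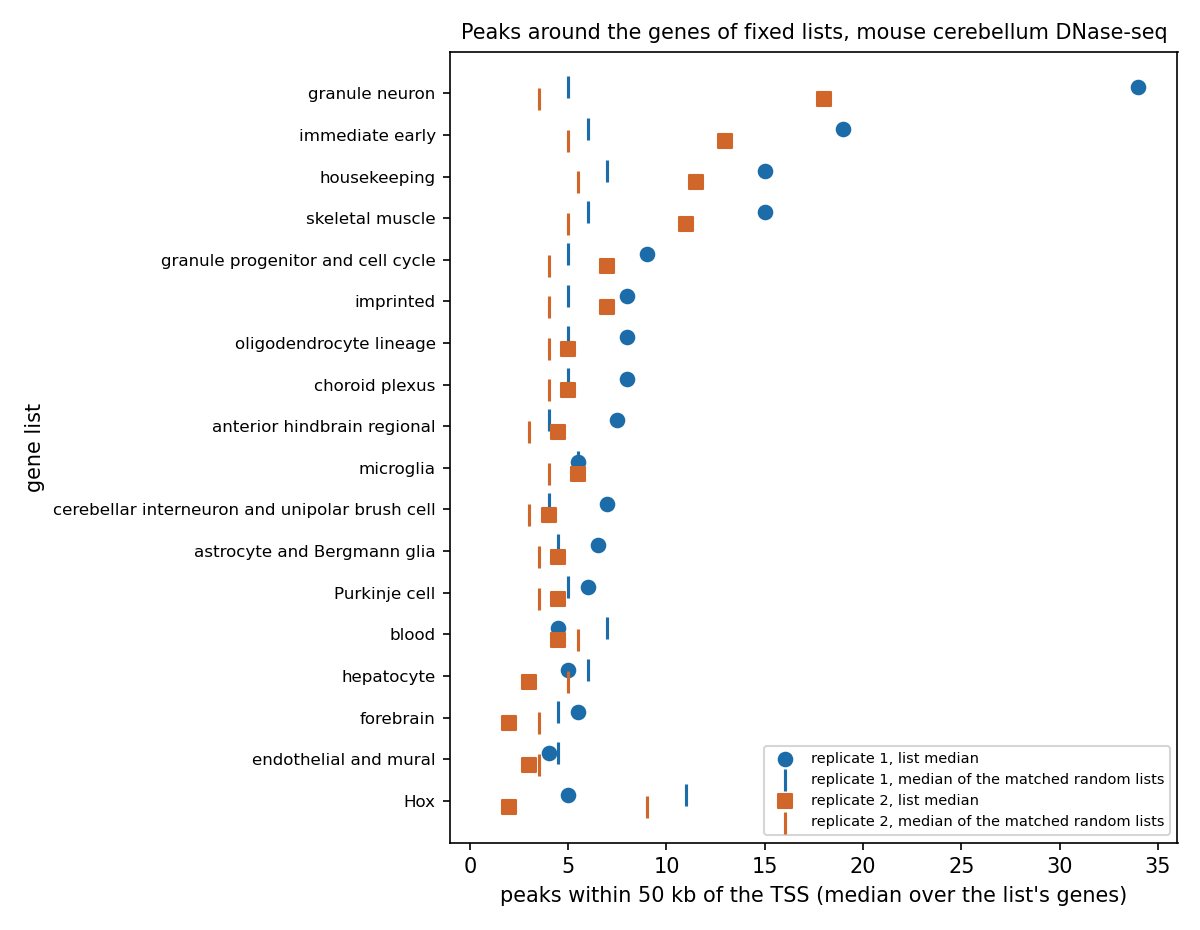
Median number of peaks within 50 kb of the TSS (x axis) over the genes of each fixed list in replicate 1 (circles) and replicate 2 (squares), beside the median of random lists matched on gene density (vertical ticks). Granule neuron genes have medians of 34 and 18 peaks against 5 and 3.5 in random lists.

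Around Neurod1, 30 peaks of replicate 1 and 19 of replicate 2 lay within 50 kb of the TSS at 79456751 of chromosome 2 (mm10, minus strand). The promoter peak spans 79456561 to 79457000 in replicate 1, with a value of 9.70, and 79456601 to 79457000 in replicate 2, with a value of 16.6. The 95% Poisson intervals, which cover counting error only and rest on the inferred step, were 9.34 to 10.1 and 16.04 to 17.2. The peak overlaps the first exon of Neurod1 (79456551 to 79456751) and the first exon of Cerkl (79456551 to 79456785). Cerkl lies on the same strand and spans 79330543 to 79456785, so Neurod1 lies inside it. The peak thus covers the annotated 5' ends of both genes. A footprint of replicate 1 at 79456973 to 79456991, upstream of both exons, overlaps a footprint of replicate 2. With 5 bp added on both sides it reads AAGAAAGTGGCCCATCTGTCGCCAGTTAG, and positions 79456979 to 79456986 (CCATCTGT) match the E-box consensus of NEUROD and ATOH1. The promoter peak of Neurod2 on chromosome 11 holds a footprint at 98329744 to 98329764 with the same match, in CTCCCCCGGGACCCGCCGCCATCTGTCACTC. These footprints were chosen after the values were seen, and these were the 2 of 20 granule neuron genes with a shared promoter footprint of this motif.

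**Figure D3:**
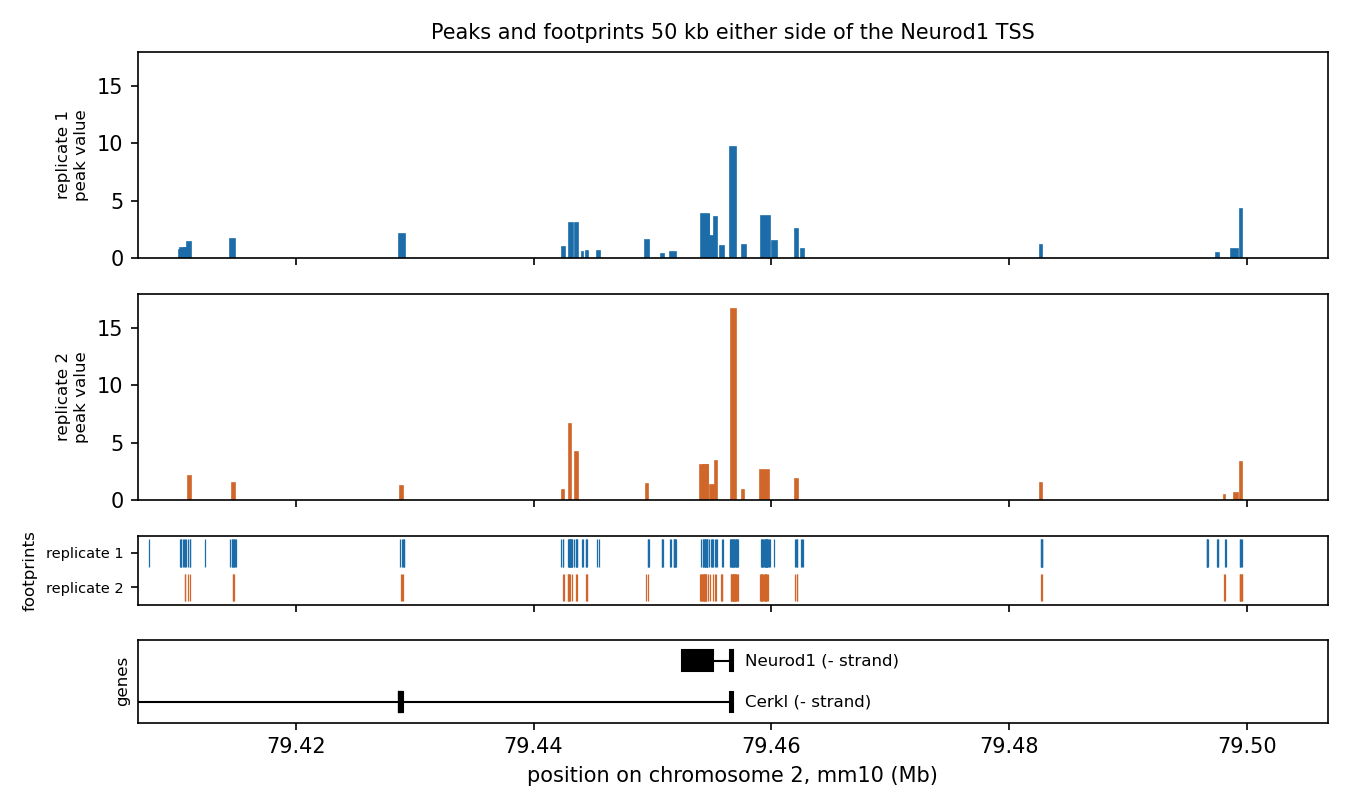
Peaks of each replicate (bars, height is the deposited peak value), footprints (ticks) and gene models 50 kb either side of the Neurod1 TSS (x axis, position on chromosome 2 of mm10 in Mb). The Neurod1 promoter peak has a value of 9.70 in replicate 1 and 16.6 in replicate 2.

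The 10 protein-coding genes with most shared peaks within 50 kb included 9 neighbours on chromosome 7. These were Cracr2b (60 shared peaks), Pnpla2 (59), Rplp2 (59), Cd151 (58), Polr2l (57), Tspan4 (57), Pidd1 (55), Slc25a22 (55) and Cend1 (49). Their TSS lie between 141429491 and 141475240, so their windows overlap and count many of the same peaks. The remaining gene was Plekhj1 on chromosome 10 (48 shared peaks), with a promoter value of 12.1 ± 0.889 (SD, n = 2). Pnpla2, a triglyceride lipase, stood at 5.62 ± 0.415, and Slc25a22, a mitochondrial glutamate carrier, at 8.51 ± 2.56. Polr2l and Tspan4 share a promoter peak.

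Most peaks lay away from promoters. Within 500 bp of a protein-coding TSS lay 22.2% of peaks in replicate 1 and 28.4% in replicate 2 (25.3 ± 4.39%, SD, n = 2), against 3.76 ± 0.0343% after moving the peaks 1 Mb. Of the remainder, introns held 38.7% and 33.7% of all peaks, intergenic sequence 32.2% and 31.4%, and coding exons 3.76% and 3.74%. The median value was 2.44 and 2.64 in TSS windows, 0.748 and 1.06 in introns, and 0.713 and 0.955 in intergenic sequence. Of 21938 protein-coding genes, 14060 (64.1%) had a promoter peak in replicate 1, 13326 (60.7%) in replicate 2 and 13218 in both. The mean TSS share was 30.7% within 1000 bp and 34.9% among the 50000 strongest peaks.

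Strong peaks were shared by both animals and weak peaks of replicate 1 often were not. In the lowest quartile of values, 17.7% of the peaks of replicate 1 and 68.0% of those of replicate 2 overlapped a peak of the other library. In the highest quartile the shares were 99.0% and 99.1%. Over all peaks they were 61.1% and 88.1% (74.6 ± 19.1%, SD, n = 2), against 1.93% and 2.75% after moving the peaks 1 Mb. Across 63657 pairs of shared peaks, which are regions and not independent replicates, log2 values had a Pearson r of 0.941 and a Spearman rho of 0.938. The median log2 ratio of replicate 1 to replicate 2 was 0.07.

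Peaks that overlapped no peak in either list of the other library numbered 24574 (22.9%) in replicate 1 and 5929 (7.84%) in replicate 2, with median values of 0.379 and 0.502. The 5 strongest of replicate 1 lay in the TSS windows of Tmpo (11.2), Tmem170 (10.8), Baz1b (10.4), Pgap2 (10.3) and Ino80 (10.03). Those of replicate 2 lay in the TSS windows of Banp (13.9), Hsph1 (10.99), Lsm4 (10.6) and Polr2b (10.4), and in intergenic sequence 214599 bp from the TSS of Rngtt (10.2). The Tmpo peak is at 91181401 to 91181640 of chromosome 10 and the Banp peak at 121950021 to 121950280 of chromosome 8. Each of these 10 peaks had a peak of the other library at most 60 bp away.

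At promoters, granule neuron genes had a lower value in replicate 1 than in replicate 2, relative to all shared peaks. Their median log2 ratio of replicate 1 to replicate 2 was -0.34 over 20 peaks, at percentile 0.67 among random lists matched on mean value. That of anterior hindbrain genes was -0.46 over 6 peaks, at percentile 0.28. The other 10 lists with enough shared promoter peaks lay between percentiles 15.2 and 94.1. Over all shared peaks within 50 kb both medians changed sign, to 0.07 for granule neurons (percentile 95.2) and 0.21 for the anterior hindbrain. Over these peaks 8 of 18 lists lay outside the central 95%, of which Hox, microglia and hepatocyte had too few shared promoter peaks for the first comparison. Hox (0.78), forebrain (0.32), microglia (0.26), anterior hindbrain (0.21), oligodendrocyte (0.19), hepatocyte (0.18) and Purkinje cell (0.13) lists were above it, and housekeeping genes (-0.16) below. Random lists were drawn peak by peak, while peaks around a gene are neighbours. The range of random lists within 50 kb may therefore be too narrow. These percentiles describe 2 libraries and carry no replicate test.

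Footprints, short stretches protected from cleavage, numbered 543535 in replicate 1 and 361298 in replicate 2, with median widths of 9 and 10 bp. Of these, 37.3% and 57.2% overlapped a footprint of the other library (47.2 ± 14.1%, SD, n = 2). Among footprints moved 75 bp that still touched a peak the shares were 36.9% and 46.2%, but those exclude footprints far from peaks. For footprints that lay in peaks of both libraries before and after the move, 65.2% and 70.4% were shared in place and 51.1% and 53.9% after the move, a ratio of 1.28 and 1.31.

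The E-box of NEUROD and ATOH1, factors of the granule neuron lineage, was found in 1.081% of footprints in replicate 1 and 1.41% in replicate 2. In windows moved 75 bp it was found in 0.258% and 0.252%, a ratio of 4.90 ± 1.01 (SD, n = 2). The motif of ZIC, zinc-finger factors of granule neurons, had a ratio of 3.66 ± 0.385, and the CAGCTG E-box 1.55 ± 0.0384. CTCF, the insulator protein, had the largest ratio (250.2 ± 9.19), followed by NFI (104.4 ± 77.7), but the moved windows held only 16 and 14 matches of CTCF and 25 and 7 of NFI. These sizes depend on the control. CTCF stood at 509.3 and 645.6 with windows moved 150 bp, and at 1329 and 1593 without the extension. Against shuffled footprint sequence NEUROD and ATOH1 stood at 12.3 and 14.3, and YY1 (53.2 and 70.8) was above NFI (34.7 and 40.9). The ratio was 20.5 ± 1.36 for NRF1, 17.7 ± 5.89 for CRE, 17.7 ± 3.87 for RFX, 10.04 ± 0.515 for SP/KLF and 7.84 ± 3.28 for YY1. It was 5.61 ± 0.0485 for OLIG, 4.16 ± 0.253 for the USF E-box, 3.52 ± 0.0391 for ETS and 2.22 ± 0.177 for NFY. FOX (0.378 ± 0.0429), GATA (0.434 ± 0.00840), homeobox (0.515 ± 0.0677) and NR4A (0.752 ± 0.0366) motifs were less frequent in footprints than in moved windows.

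Of 27 motifs, these 14 were higher and 4 lower in both libraries by Fisher's exact test (two-sided, Benjamini-Hochberg over motifs and replicates; footprints are not independent replicates). The largest adjusted p among the higher motifs was 1.7e-07, for OLIG, and among the lower 0.0064, for NR4A (exact test). Against footprint sequences shuffled within themselves 22 motifs were higher, the same 14 among them. NR4A was then among the higher motifs, and homeobox was no longer lower in both libraries. NR4A was also no longer among the lower motifs without the extension or for footprints of both replicates. The sequence preference of DNase I was not corrected here.

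**Figure D4:**
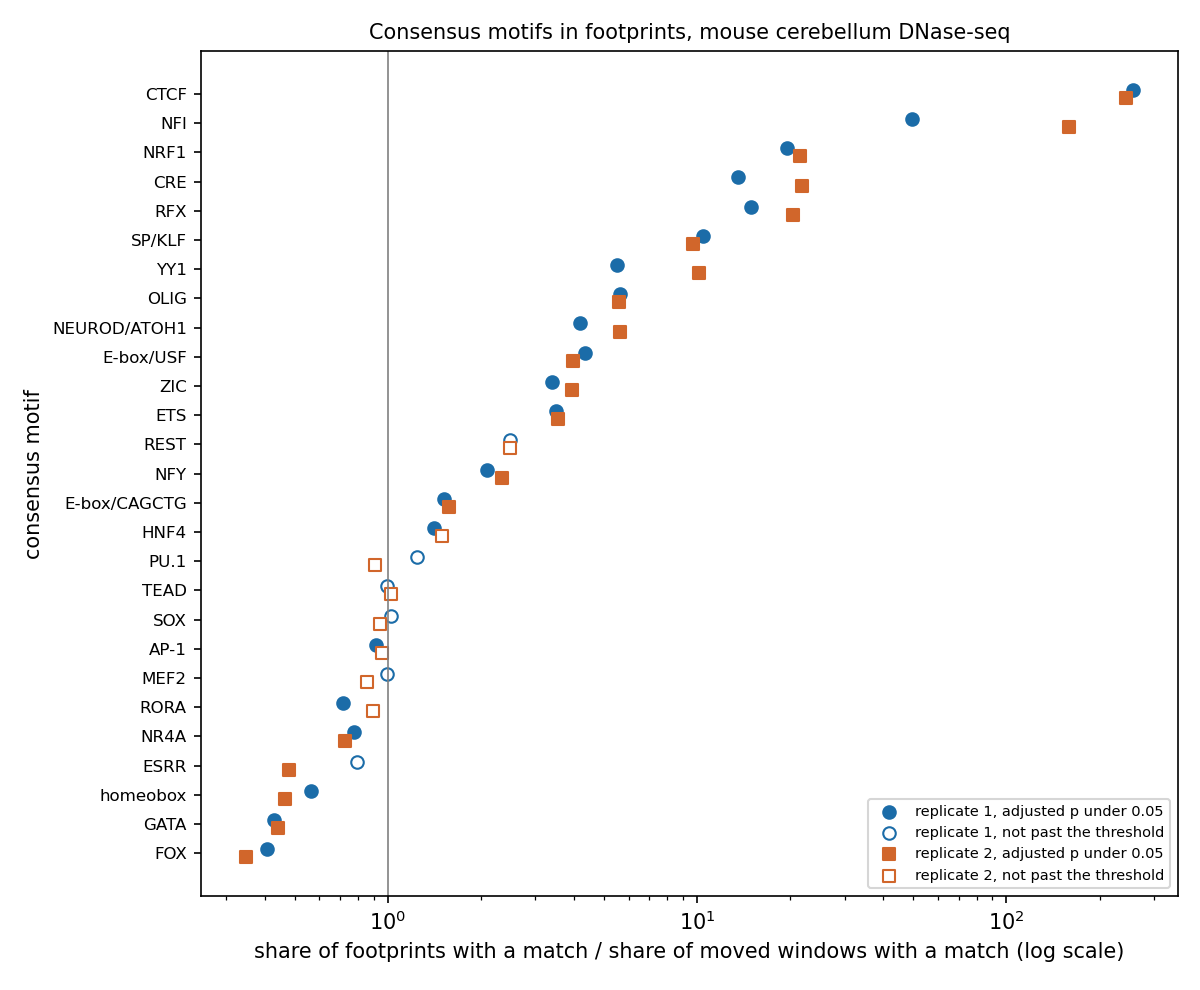
Share of footprints with a consensus match divided by the share of windows moved 75 bp (x axis, log scale) for 27 motifs in replicate 1 (circles) and replicate 2 (squares), filled where the adjusted p of Fisher's exact test is under 0.05. CTCF lies at 256.7 and 243.7, and FOX at 0.408 and 0.347.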

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

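Both tests of the Y chromosome peaks were set before their results were seen, and none in this part was chosen only afterwards. Peaks on the Y chromosome were singled out because the mice are labelled female; they are part of the peak lists compared above, but no comparison was made of them. Replicate 1 had 28 such peaks and replicate 2 had 31, with 22 of each overlapping a Y peak of the other library. Their median value was 0.417 and 0.690, against 0.861 and 1.21 over each whole list.

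Male cells in the sample are argued against by the promoters of Ddx3y, Eif2s3y, Kdm5d and Uty, of which 0 had a peak even in the longer lists, although a small share of male cells could stay under the calling threshold. Reads shared with near-identical copies outside the Y chromosome stay open. Of the 59 Y peaks, which count shared sites in both libraries so that the interval is too narrow, 40 (67.8%, exact 95% interval 54.4 to 79.4) had a match of at least 50 bp at 95% identity on another chromosome, against 37.2% (33.0 to 41.6) of 500 random Y windows. That is above random Y sequence but under the 80% set in advance, so shared reads may account for some of these peaks but are not shown to account for all. The design has no male group, and no biological explanation was tested.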

How the results depend on the processing

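The alternatives that used FDR positions, the 5' end of the gene alone or merged overlapping peaks were chosen after seeing the data, and all others before. The correlation of shared peaks was 0.939 with a reciprocal overlap of 50%, outside its narrow interval (0.9405 to 0.9422) but close in size. The TSS share was 30.7% within 1000 bp and 34.9% among the 50000 strongest peaks; the wider window takes in more sequence by construction, and for the strongest peaks the cause was not tested. Of the lists with more promoter peaks than other genes, 1 rather than 4 stood above lists matched on promoter CpG content, where the other 3, at the maximum of 100% in replicate 1, could not have passed, and 4 rather than 7 lists were lower with the longer peak list, the cause of which was not tested. For peaks within 50 kb, 0 lists rather than 1 (Hox) lay below random lists in both libraries when only distal peaks were counted, and 0 when lists were not matched on gene density, where Hox genes were lower in replicate 2 alone. For value ratios between replicates, 8 of 18 lists rather than 2 of 12 stood apart over all shared peaks within 50 kb, in part because 3 of the 8 had too few promoter peaks before, and granule neurons turned from -0.34 to 0.069 and the anterior hindbrain from -0.46 to 0.21; the cause was not tested. Footprint sharing was 33.0% with a reciprocal overlap of 50%, which is stricter by construction, and 65.8% for footprints inside peaks of both libraries, which leaves out sites called open in 1 library. Against shuffled sequence 22 rather than 14 motifs were higher and 2 rather than 4 lower, the cause of which was not tested. Among the odds ratios of single lists in single libraries under the settings chosen before, 97 stayed on their side of the threshold, 7 lost it and 4 gained it. The other counts and shares stayed within 1.5 times or 1 SD of the reported value. A count can stay while its members change. Against lists matched on promoter CpG content, 5 rather than 7 lists were lower, and only 3 of the 7 were among them. For peak sharing the SD (19.1%) is the wide spread between the libraries, so large changes count as within it. Sharing was 61.1% and 88.1% as reported, 49.8% and 70.8% with a reciprocal overlap of 50%, and 87.1% and 88.2% among the 50000 strongest peaks. With either replicate left out, a share is that of the other library and lies within 1 SD by construction, which says nothing about stability. Depth sets the counting error: on the inferred scale, the 24574 peaks of replicate 1 with no counterpart in replicate 2 had a median of 110 cleavages, against 250 over all its peaks.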

Other observations

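The split of motifs by place and the test of forebrain and Hox promoters were chosen only after the main results were seen, and the other tests in this part before. Motif shares in footprints away from start sites and at promoters were set side by side. Among footprints over 1 kb from every TSS, the E-box of NEUROD and ATOH1 was found in 1.54% in replicate 1 and 2.22% in replicate 2, 5.81 ± 1.26 times the share of moved windows (SD, n = 2). Within 500 bp of a TSS it was found in 0.278% and 0.316%, 2.29 ± 0.146 times that of moved windows. The ZIC motif (0.777 ± 0.0921% distal and 0.230 ± 0.0219% at promoters), NFI (0.456 ± 0.124% and 0.108 ± 0.0165%) and CTCF (1.53 ± 0.346% and 0.245 ± 0.0254%) likewise had larger shares at distal footprints. NRF1 was found in 1.197 ± 0.193% of promoter footprints and 0.0842 ± 0.0173% of distal footprints, and SP/KLF in 2.95 ± 0.279% and 0.263 ± 0.0204%. The CAGCTG E-box stood above moved windows at distal footprints (ratios 1.84 and 1.98) but not at promoters (0.964 and 0.914). ETS stood above them at promoters (3.70 and 3.53), while its distal ratios were 1.56 and 1.19, the latter not past the threshold (adjusted p = 0.52, exact test). The difference in share between places was larger than the spread between the libraries for each of these motifs, but was not itself tested, and promoters are richer in CpG. The ratio to moved windows was alike in both places for NRF1 (19.8 ± 4.29 at promoters and 17.6 ± 0.334 distal). It overlapped for NFI (71.6 ± 66.8 and 98.6 ± 58.0). It differed for ZIC (1.94 ± 0.390 and 4.58 ± 0.655) and SP/KLF (10.9 ± 0.496 and 4.39 ± 0.702). For CTCF it was 113.1 ± 24.7 and 324.0 ± 82.1. The moved windows held only 3 and 2 CTCF matches at promoters and 10 and 12 at distal sites, so this difference is not settled.

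Promoters on the X chromosome had lower values than autosomal promoters matched on CpG content, by a median log2 difference of -0.88 in replicate 1 (bootstrap 95% interval -1.07 to -0.76) and -0.71 in replicate 2 (-0.88 to -0.52), a mean of -0.80. Single autosomes lay between -0.17 and 0.14 in replicate 1 and between -0.34 and 0.25 in replicate 2. As a hypothesis, a silent X chromosome in each female cell may lower these values, since both differences lay in the range set in advance for it. Genes known to escape silencing stood above other X genes, at percentile 100 of random X lists in both libraries: Kdm6a at 22.8 ± 11.4 (SD, n = 2), Kdm5c at 11.7 ± 4.01, Ddx3x at 9.75 ± 0.848, Eif2s3x at 6.91 ± 1.63 and Pbdc1 at 6.39 ± 0.305. Their medians were 8.89 and 10.3, and those of the housekeeping list were 10.2 and 13.6. High values thus need not reflect escape, and this comparison does not decide on silencing. X genes also had a promoter peak less often than autosomal genes (49.4% and 45.1%, against 65.3% and 62.0%). A lower value for all X sequence stays open. Distal X peaks also lay lower, by a mean of -0.47 (-0.42 and -0.52). The bound set in advance for this explanation, a distal difference close to that of promoters, was met in replicate 2 alone. A silent X chromosome could lower distal peaks as well, so their lower values do not separate these explanations.

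Replicate 1 had more peaks than replicate 2. A smaller share of cleavages inside accessible sites in replicate 2 is argued against by the 10000 strongest shared peaks, the set chosen in advance, whose median log2 ratio of replicate 1 to replicate 2 was -0.17 (bootstrap 95% interval -0.18 to -0.16); over all shared peaks, for which no bound was set, it was 0.07. Lower depth in replicate 2 may leave weak sites uncalled: peaks of replicate 1 without a counterpart had a median count of 70.3 when scaled to the depth of replicate 2, below the lower quartile (124) of its shorter list. That quartile is not a calling threshold, since the shorter list holds counts down to 8. The median value of these peaks, 0.379, was about the lower quartile of the longer list of replicate 2 (0.378). Peaks of replicate 2 without a counterpart were weak as well (median value 0.502, against 1.21 over its shorter list), so weakness does not single out depth. Of forebrain genes, 8 of 11 had no peak in replicate 2 (72.7%, against a median of 36.4% in genes matched on value and CpG, percentile 99.53), and of Hox genes 4 of 5 (percentile 99.56), but the forebrain list was chosen because its loss had been seen and the percentiles are not adjusted for the number of lists, so they do not decide whether these were lost like other weak promoters. Over shared peaks within 50 kb, forebrain (0.32) and Hox (0.78) lists also had higher values in replicate 1, as did other lists, among them anterior hindbrain and oligodendrocyte. A difference in dissection or in cells between the animals was not tested, and no biological explanation was tested.

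Some strong peaks had no overlap in either list of the other library, 217 in replicate 1 and 168 in replicate 2 in the top quartile of values. Nearly all such peaks, 97.2% in replicate 1 and 100% in replicate 2, touched a position at an FDR of 0.001 or lower in the other library. A touch of 1 bp was enough, so it can be the edge of a neighbouring open stretch. Each of the strongest such peaks, named above, reached this FDR over its whole width in the other library. A neighbouring peak of the other library lay within 500 bp of 98.2% and 99.4%, against 7.37% and 10.7% after moving them 1 Mb. These peaks may thus reflect where the caller placed or divided peaks within a wider open site, and not a site open in 1 animal alone. The design gives no group to set against this, and no biological explanation was tested.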
